A study of Arabidopsis thaliana with 14 samples.

How the data were processed

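RNA-seq and ChIP-seq of Arabidopsis thaliana seedlings (C24 ecotype, 10 days old) covered 14 samples, of which 4 were RNA libraries (2 TWT, 2 fen1) and 10 were ChIP or input libraries with 1 library per mark and genotype. Samples were grouped by genotype and assay from their titles. The labels do not say whether the 2 RNA libraries of a genotype came from separate cultures. How the authors' test used the 2 libraries is not given either. Any spread between libraries behind the p-values may therefore be technical.

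The submitters' processing notes name Bowtie 0.12.9, SAMtools, TopHat2 2.1.1 and Cuffdiff 2.1.1 and the TAIR10 genome, with no role or order. Strand handling, the treatment of reads that match several places and the filters used are not given in the sources used here. The deposited RNA table gives 1 value per genotype, and its layout is that of Cuffdiff, so the values were read as FPKM (fragments scaled to transcript length and to library size) that the authors scaled and combined over the libraries of a genotype. The header does not name the unit. The deposited log2 fold changes are fen1 over TWT with no pseudocount, and they matched the ratio of the 2 FPKM columns within 1.17e-05 wherever both genotypes were above 0. They are undefined for 5 genes listed at 0 in TWT and 5 listed at 0 in fen1. The authors' deposited p-value has a floor of 5e-05, which 582 genes share, and their smallest q-value is 0.00173 for that reason. All 1114 genes of the table are marked significant, with q up to 0.0497. The q-value times the rank over the p-value gave 20132 tests at every gene, so the list of significant genes appears complete, but genes not called have no value.

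The 3 deposited peak lists (TWT H3K27me3, H3K4me3 and H3K9me2) give each peak's position and a score, which is the authors' own value from the peak caller, with a floor near 50. Peak names in the files point to MACS; its version, its control library and its settings are not given in the sources used here. Each list represents 1 library. BED starts were converted to 1-based positions. The fen1 ChIP libraries, the H3 libraries and the inputs were not analysed here, so no mark was compared between genotypes. Read depth per library is unknown, and no values per library were used, so neither the precision of single FPKM values nor the effect of leaving out a library could be computed. Genes of low FPKM or short length rest on fewer reads and are less certain.

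A gene was called where the authors' deposited q was under 0.05, and no test of differential expression was added, since no counts or values per library were used. No pseudocount enters the fold changes given. Gene symbols came from a reference table of the TAIR10.1 assembly, which was used only for names, synonyms and gene order, with 1113 of 1114 identifiers matched. Coordinates are those of the authors' table and peak lists.

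The 15 gene lists held 271 entries, of which 5 were dropped because the reference gives another symbol, and 13 were kept although it gives none. Members called higher and called lower were tested against all 20132 tested genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 30 tests. All members were taken as tested, since the table does not say which were; this makes a high share harder to call and gives no meaning to a low one. The count adjusted over the list alone gave members outside the table a p of 1. It reuses the authors' p-values, cannot exceed the number called, and equalled it for every list. It is therefore no separate check of a list. The planned percentile of each list's median fold change was not computed, because members outside the table have no value.

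A gene carried a mark where a peak overlapped its body by at least 1 bp. The planned comparison of called genes with genes tested and not called was replaced by higher against lower genes, as the latter kind has no coordinates in the table. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only, and were compared with Fisher's exact test, two-sided, adjusted over 3 marks. TWT levels by mark were compared on the log2(FPKM + 1) scale with 100000 permutations of genes, for groups of at least 10 genes. Peak overlaps were compared with 1000 random placements on the same chromosome. Bins of 1 Mb were ranked by H3K9me2 cover and the top 20% were compared with the rest, again between higher and lower genes, each gene placed by its midpoint.

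The rule for naming genes was fixed before the data were examined. It names FEN1 and up to 4 called members per list by smallest q and then largest change. It also names the 10 largest rises and 10 largest falls among called genes with at least 1 FPKM in one genotype and above 0 in both. Fixed members of the Polycomb, silencing and DNA damage lists were added, as were the 3 largest changes in each direction per mark and the transposable element genes. A gene that this rule names is not reported here. TSO2, named for its level, CYP71A13 and the genes first named in the closing section were chosen after their values were seen. The genes near GRP-3 (GRP3S, GRP9, AT2G05510 and AT2G05540) and PSAD-2, PSAF, FED A and LHB1B1 also fall outside the rule.

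Alternatives were a q under 0.01, a minimum 2-fold change, a minimum of 1 FPKM in one genotype, pseudocounts of 0.1, 1 and 5, stricter or wider overlap of peaks with genes, the peaks of higher score, and the top 10% of bins. The minimum 2-fold change kept the 10 genes at 0 in one genotype, which have no finite fold change. Added after seeing the data were the dropped list members, a peak score of at least 100, quartiles of mean expression, and leaving out chromosome 2.

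The list test was tested on simulated data of 20132 genes and a list of 27, with 500 draws per setting and Bonferroni correction for 30 tests. The list was called in 0.2% of draws with no planted change, and in 43.2% and 98% of draws when 20% and 40% of its members were called. Members were drawn independently, as Fisher's exact test assumes, so these rates do not cover lists whose members rise or fall together. The number of tests was recovered as 20132 from simulated p and q values, and the overlap code gave the same result as a base-by-base count for all 300 simulated intervals. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.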

Results

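Whole Arabidopsis thaliana seedlings of the C24 ecotype, 10 days old and grown on plates without further treatment, were compared between a fen1 mutant and the transgenic wild type (TWT) that served as its control. FEN1 encodes flap endonuclease 1, which removes the 5′ flaps left on DNA during replication and repair. RNA was sequenced from 2 libraries of each genotype. Chromatin immunoprecipitation (ChIP) was sequenced for H3K27me3, the mark of Polycomb silencing, for H3K4me3, a mark of active promoters, and for H3K9me2, a mark of silent heterochromatin, with 1 library per mark and genotype. The RNA data consisted of the authors' deposited table of 1114 genes, with 1 FPKM value per genotype and the authors' test, and the chromatin data of 1 TWT peak list for each of the 3 marks. The fen1 ChIP libraries, the H3 libraries and the input libraries were not analysed here. Read depth per library was not known from these files, and no value per RNA library was used, so the spread between replicates cannot be shown for any gene. The table held 1 FPKM value per genotype, so no SD stands beside the levels given here, and significance is that of the authors' own test.

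The comparison of fen1 with TWT RNA asked which transcripts depend on FEN1. In fen1 seedlings 684 genes were higher and 430 were lower, and the genes of the DNA damage response were prominent among those that rose. SMR7, a cell cycle inhibitor induced by DNA damage, rose from 5.50 to 70.7 FPKM in the authors' deposited table (log2 fold change 3.68, q = 0.00173). BRCA1, which acts in homologous recombination, rose from 5.29 to 28.3 FPKM in the authors' deposited table (log2 2.42, q = 0.00173). Of called genes above 0 in both genotypes and with at least 1 FPKM in one, the glutathione transferase gene GSTF14 fell most. It went from 64.7 to 0.54 FPKM in the authors' deposited table (log2 −6.91, q = 0.00173). The glycine-rich protein gene GRP-3 came next, from 2033 to 35.6 FPKM in the authors' deposited table (log2 −5.83, q = 0.00173).

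FEN1 itself (AT5G26680, chromosome 5, 9311875 to 9315475, TAIR10) was higher in the mutant, at 22.7 FPKM against 14.5 FPKM in TWT in the authors' deposited table (log2 0.65, q = 0.00462). The labels do not say what kind of mutation fen1 is, so a transcript level above that of TWT neither checks nor contradicts the genotype.

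Of the 20132 genes that the authors' p and q values imply were tested, 5.53% were listed as changed. The median log2 fold change in the authors' deposited table was 0.95 for the 684 higher genes and −0.72 for the 430 lower genes. Of the genes above 0 in both genotypes, 320 higher genes and 127 lower genes changed at least 2-fold, and 21 and 11 at least 8-fold. The median level in the authors' deposited table was 6.56 FPKM in TWT and 14.6 FPKM in fen1 for the higher genes, and 20.7 FPKM in TWT and 11.6 FPKM in fen1 for the lower genes. By annotated type, 1097 of the 1114 were protein-coding genes, 9 other RNAs, 4 pseudogenes, 2 transposable element genes, 1 an rRNA and 1 a miRNA gene.

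Among genes with at least 1 FPKM in one genotype, the gene with the largest rise in the authors' deposited table was CRU3, which encodes the seed storage protein cruciferin, from 0.33 to 7.65 FPKM (log2 4.53, on the FPKM ratio with no pseudocount). GEX1, a gamete-expressed gene, rose by a log2 of 4.20 and the cupin gene AT5G38910 by 3.99 in the authors' deposited table. BHLH100, a transcription factor gene induced by low iron, went from 1.91 to 28.4 FPKM in the authors' deposited table (log2 3.89). The cytochrome P450 genes CYP82C2 and CYP71A12, both of indole defence metabolism, rose by a log2 of 3.82 and 3.66 in the authors' deposited table. The order of low genes depends on that scale: with log2(FPKM + 1), CRU3 stood at 2.70 and GEX1 at 1.56, below AT5G38910 at 3.76, CYP71A12 at 3.48, SMR7 at 3.46 and BHLH100 at 3.33. The other genes of the 10 largest rises in the authors' deposited table were AT1G47980 (log2 3.87), AT2G30660 (log2 3.87), the berberine-type oxidase gene AT1G26410 (log2 3.70) and SMR7. CYP71A12 has a close copy, CYP71A13, a short distance away, and how reads were divided between them is not given in the sources used here.

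After GSTF14 and GRP-3, the largest falls in the authors' deposited table were those of the RNA gene AT1G67105 (log2 −5.65), the extensin gene EXT6 (log2 −4.37) and AT2G33830, of the dormancy and auxin associated family, from 155 to 9.10 FPKM (log2 −4.09). The extensin-like gene AT4G08410 changed by a log2 of −3.88 in the authors' deposited table, AT3G28320 by −3.38, the berberine-type oxidase gene AT5G44440 by −3.32, the auxin-induced root gene AIR1 by −3.31 and the ankyrin repeat gene AT4G11000 by −3.15. With log2(FPKM + 1) GRP-3 stood at −5.80, beyond GSTF14 at −5.42, AT2G33830 at −3.95, beyond EXT6 at −3.38, and AT4G08410 at −1.18. Extensin genes share similar repeats, so the levels of EXT6 and AT4G08410 are uncertain. GRP-3 lies near other glycine-rich protein genes on chromosome 2. Of these, GRP3S rose from 731 to 1263 FPKM and GRP9 fell from 247 to 89.0 FPKM in the authors' deposited table. The nearby genes AT2G05510 and AT2G05540 changed by a log2 of −2.18 and −1.24. How reads were divided among such genes is not given in the sources used here, so the level of GRP-3 is uncertain too. A further 5 genes were listed at 0 in TWT and 5 at 0 in fen1, and no fold change can be given for these.

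The 15 gene lists fixed before the data were examined asked which cell functions moved in fen1. The DNA damage response list rose as a group, with 16 of its 27 genes called higher, none called lower and 11 not called, where 0.92 higher genes would be drawn by chance. Fisher's exact test, two-sided, gave an adjusted p of 7.33e-16 over the 30 tests of lists and directions. Adjusted over the list alone, 16 genes were called, a count that cannot exceed the number called above. The 16 log2 fold changes in the authors' deposited table ran from 0.53 to 3.68, with a median of 1.47. GMI1, which responds to gamma irradiation, rose by a log2 of 2.06 and the transcription factor gene NAC044 by 1.93 in the authors' deposited table. PARP2, a poly(ADP-ribose) polymerase, went from 6.73 to 24.0 FPKM in the authors' deposited table (log2 1.84). CYCB1;1, the mitotic cyclin that accumulates after DNA breaks, went from 8.64 to 22.0 FPKM in the authors' deposited table (log2 1.35). TSO2, a ribonucleotide reductase subunit that makes deoxynucleotides, was the most abundant of these in fen1, at 328 FPKM against 96.9 FPKM in TWT in the authors' deposited table.

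The lists of replication and of division did not pass the test. Of 25 genes of DNA replication and chromatin assembly, 2 were called, FEN1 and TIL1, the catalytic subunit of DNA polymerase epsilon (log2 0.63 in the authors' deposited table), with an adjusted p of 0.780 by Fisher's exact test and 2 calls adjusted over the list alone. Of 18 mitotic genes, 2 were called higher, CDKB1;1 (log2 0.52) and CDC20.1 (log2 0.49) in the authors' deposited table, with an adjusted p of 0.529 by Fisher's exact test and 2 calls adjusted over the list alone. None of the 12 replication-dependent histone genes was called.

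Salicylic acid and defence genes moved both ways. Of 20 genes, 4 were called higher (adjusted p = 0.0394, Fisher's exact test) and 4 lower (adjusted p = 0.0114), and 8 were called adjusted over the list alone. The defence genes PR1 and PR5 fell, PR1 from 28.7 to 5.67 FPKM (log2 −2.34) and PR5 from 29.8 to 12.0 FPKM (log2 −1.31) in the authors' deposited table. PBS3, an enzyme of salicylic acid synthesis, rose by a log2 of 1.15 and CBP60G, a transcription factor that drives that synthesis, by 0.98 in the authors' deposited table. Neither direction passed when at least 2-fold changes were required, with 2 genes higher (adjusted p = 0.245, Fisher's exact test) and 2 lower (adjusted p = 0.0750).

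Seed and embryo markers were called higher in 3 of 11 cases (adjusted p = 0.0394, Fisher's exact test), with 3 calls adjusted over the list alone. These were CRU3, the cruciferin gene CRA1 (2.61 to 12.0 FPKM, 4.60-fold) and the oleosin gene OLEO2 (0.96 to 3.62 FPKM, log2 1.92) in the authors' deposited table, all 3 below 3 FPKM in TWT. At a q under 0.01 only 2 were left and the list no longer passed (adjusted p = 0.174, Fisher's exact test). Of 13 root markers, EXPA7, an expansin of root hairs, was the 1 gene called (log2 1.36 in the authors' deposited table; adjusted p = 1 for the list, Fisher's exact test; 1 call adjusted over the list alone). Of 13 cold and drought genes, RD29B (log2 1.77) and LTI30 (log2 1.04) were higher and RD29A (13.6 to 6.81 FPKM) and COR15B (log2 −0.91) lower in the authors' deposited table. Neither direction passed for that list (adjusted p = 0.351 and 0.182, Fisher's exact test; 4 calls adjusted over the list alone).

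The series names transcriptional gene silencing as its subject. Of the silencing machinery list, 1 gene was called higher where 1.02 would be drawn by chance. Among 30 genes of the silencing machinery only the DNA methyltransferase gene CMT3 was called (log2 0.46 in the authors' deposited table; adjusted p = 1, Fisher's exact test; 1 call adjusted over the list alone). MET1, DDM1 and ROS1 were not listed as changed. None of the 5 genes known to be silenced by DNA methylation and none of the 14 Polycomb and Trithorax components was called. Of 34 Polycomb targets, the flower identity genes SEP3 and STK were called higher (adjusted p = 1, Fisher's exact test; 2 calls adjusted over the list alone). SEP3 rose from 1.33 to 3.58 FPKM (log2 1.43) and STK was listed at 0 in TWT and at 1.03 FPKM in fen1 in the authors' deposited table. Both carried a TWT H3K27me3 peak and neither of the other marks. AG, AP1, FT, FLC and SOC1 were not listed. No gene was called of 11 heat shock genes, 14 genes of flavonoid synthesis or 19 photosynthesis genes. Some photosynthesis genes outside that list, named after their values were seen, were lower in the authors' deposited table, among them PSAD-2 (log2 −0.42), PSAF (log2 −0.56), FED A (log2 −0.67) and LHB1B1 (log2 −0.53). These were picked from the lower genes, so they show no change of photosynthesis genes as a group. A gene outside the table may have been unchanged or too lowly expressed to be tested, and the 2 cannot be distinguished here.

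**Figure D1:**
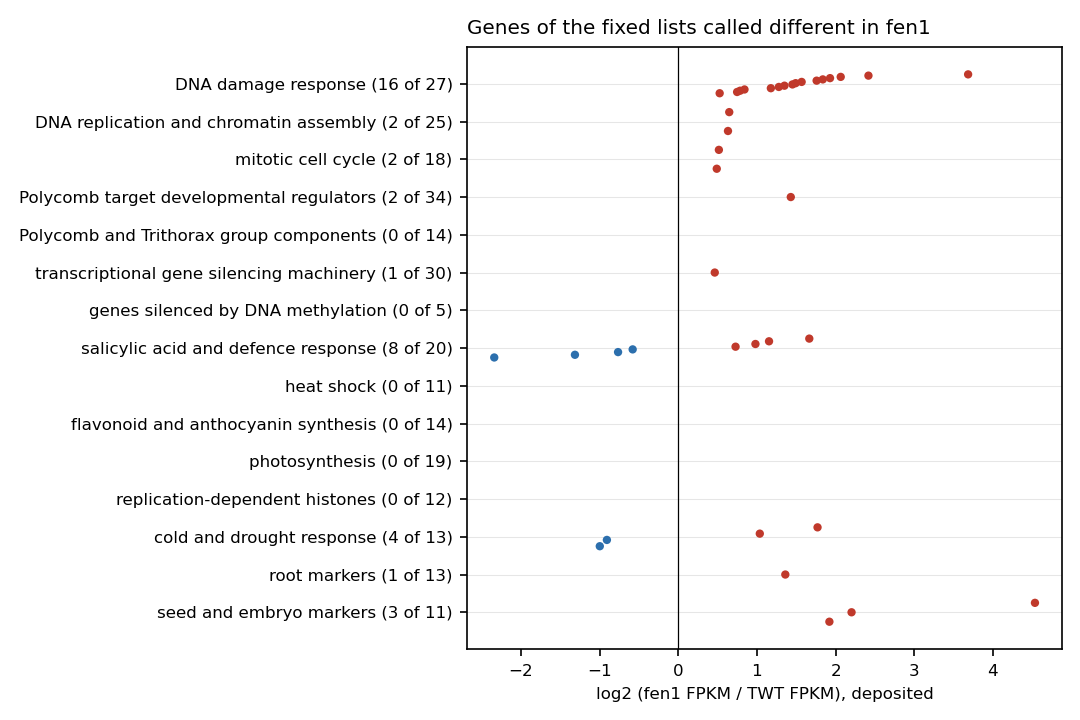
Each point is a gene of a fixed list called different in fen1, placed at the log2 of fen1 FPKM over TWT FPKM in the authors' deposited table (horizontal axis), red if higher and blue if lower, with lists as rows and the number called of the number in the list in brackets. The 16 DNA damage response genes lie between 0.53 and 3.68, all above 0, while the salicylic acid and defence list splits into 4 higher and 4 lower genes; STK, listed at 0 in TWT, has no point.

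Transposable element genes were examined for a loss of silencing. Only 2 were listed, and both were lower in fen1. AT3G17050 fell from 10.4 to 5.33 FPKM (log2 −0.96) and AT5G35777 from 0.72 to 0.23 FPKM (log2 −1.64) in the authors' deposited table. Neither carried an H3K9me2 peak in TWT, where AT3G17050 had no peak and AT5G35777 an H3K27me3 peak alone. Their falls thus do not bear on a loss of H3K9me2 silencing. No transposable element gene was listed as higher. How many transposable element genes were tested is not known from the table, so no share was computed and the planned test against protein-coding genes was not made.

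The marks that changed genes carry in TWT asked whether silenced genes were among those that rose. Genes that fell in fen1 carried the active mark H3K4me3 more often than genes that rose. An H3K4me3 peak overlapped 279 of the 430 lower genes (64.9%, exact Clopper-Pearson 95% interval 60.2 to 69.4%) and 320 of the 684 higher genes (46.8%, 43.0 to 50.6%). H3K27me3 was on 272 higher genes (39.8%, 36.1 to 43.5%) and 140 lower genes (32.6%, 28.1 to 37.2%). H3K9me2 was rare, on 20 higher genes (2.92%, 1.80 to 4.48%) and 11 lower genes (2.56%, 1.28 to 4.53%).

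By Fisher's exact test, two-sided and adjusted over 3 marks, higher and lower genes differed in H3K4me3 (adjusted p = 1.22e-08) and in H3K27me3 (adjusted p = 0.0233), and no difference in H3K9me2 was detected (adjusted p = 0.852). The H3K4me3 difference of −18.1 percentage points was −12.4 points within quartiles of mean expression, an alternative chosen after seeing the data (adjusted p = 0.00018, permutation test). Among genes changed at least 2-fold it was −6.40 points (adjusted p = 0.530, Fisher's exact test). The quartiles are of the mean over both genotypes, and at a given mean a lower gene has the higher TWT level. Over all listed genes the TWT medians were 20.7 FPKM for lower and 6.56 FPKM for higher genes. The quartiles therefore cannot separate a mark from the TWT level. The H3K27me3 difference of 7.21 points was 3.77 points within those quartiles (adjusted p = 0.302, permutation test). Among genes changed at least 2-fold it was −2.55 points (adjusted p = 0.791, Fisher's exact test). Of listed genes with H3K27me3 alone, 66.2% rose, against 78.3% of those with no peak and 51.7% of those with H3K4me3 alone. The H3K27me3 difference therefore does not show that genes with this mark rose more often than unmarked genes.

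Of the genes that rose with a TWT H3K27me3 peak, CRU3, AT5G38910 and AT1G47980 had the largest changes, and of those that fell, GSTF14, GRP-3 and EXT6. With an H3K4me3 peak the largest rises were those of GEX1, AT1G12030 (log2 3.31) and AT2G30766 (36.9 to 283 FPKM, log2 2.94) in the authors' deposited table, and the largest falls those of GRP-3, AT2G33830 and AT4G11000. With an H3K9me2 peak they were BRCA1, the ATPase gene AT3G63380 (log2 2.28) and the late embryogenesis abundant gene AT4G21020 (log2 1.88) among the rises in the authors' deposited table. The falls with an H3K9me2 peak were EXT6, AT4G08410 and AT2G05914 (log2 −2.70 in the authors' deposited table). BRCA1 (chromosome 4, start 11248078, TAIR10) and AT4G21020 (start 11228187) lie near each other, and both carried H3K27me3 as well as H3K9me2. Of the 16 called DNA damage genes, 10 carried H3K4me3, 2 H3K27me3 (BRCA1 and GMI1), 1 H3K9me2 (BRCA1) and 4 no peak. The 3 called seed genes all carried H3K27me3 alone.

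**Figure D2:**
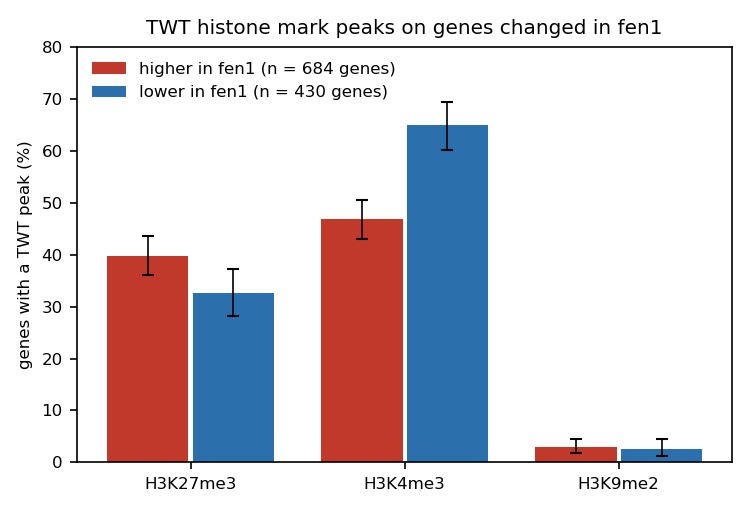
Bars give the percentage of genes higher in fen1 (red, 684 genes) and lower in fen1 (blue, 430 genes) whose body overlaps a TWT peak of each mark by at least 1 bp, and whiskers are exact 95% binomial intervals. H3K4me3 peaks were on 46.8% of higher and 64.9% of lower genes, while H3K9me2 peaks were on under 5% of either.

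The levels of the listed genes in TWT were set beside their marks. Genes with H3K4me3 alone were the most highly expressed group, with a median of 19.2 FPKM over 507 genes, against 6.01 FPKM over the 189 listed genes with no peak. The 88 genes with both H3K27me3 and H3K4me3 had a median of 11.7 FPKM, the 299 with H3K27me3 alone 5.00 FPKM and the 22 with H3K27me3 and H3K9me2 4.12 FPKM. These medians are over the authors' deposited values of changed genes and do not describe the genome. On the log2(FPKM + 1) scale the median exceeded that of genes with no peak by 1.53 for H3K4me3 alone (adjusted p = 4e-05, permutation test across genes, which are not replicates). The excess was 0.86 for both H3K27me3 and H3K4me3 (adjusted p = 0.00318, permutation test). The differences of −0.22 for H3K27me3 alone and −0.45 for H3K27me3 with H3K9me2 did not pass (adjusted p = 0.302 for both, permutation test). With peaks required to cover at least 50% of the gene body, the H3K27me3 difference was −0.54 and passed (adjusted p = 0.0001, permutation test). Among the 189 genes with no peak, 148 rose and 41 fell.

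The peaks of the 3 marks in TWT showed how far they occupy separate regions. H3K4me3 stayed apart from both silencing marks, and H3K27me3 and H3K9me2 overlapped each other more than randomly placed peaks did when all peaks were used. The lists held 15540 H3K4me3, 9239 H3K27me3 and 8051 H3K9me2 peaks, which covered 23.0, 15.2 and 11.5 Mb of the nuclear chromosomes. Of the nuclear H3K9me2 peaks, 56 (0.696%) overlapped an H3K4me3 peak, against a mean of 33.0% for 1000 random placements on the same chromosomes. Of the H3K27me3 peaks, 808 (8.78%) overlapped H3K4me3, against 36.9% for the placements. H3K27me3 peaks overlapped H3K9me2 in 2009 cases (21.8%, placements 14.2%), and H3K9me2 peaks overlapped H3K27me3 in 1901 of 8044 nuclear cases (placements 20.4%).

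Each ordered pair gave a permutation p = 0.002, two-sided, the smallest that 1000 placements can give. Each list came from 1 library, so the placements describe these libraries and carry no replicate error. With only the peaks of higher score in each list, the H3K27me3 and H3K9me2 overlaps lay below the placements, by −4.16 points for H3K27me3 peaks and −6.72 points for H3K9me2 peaks (permutation p = 0.002 for both).

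The position of changed genes asked whether higher and lower genes lay equally often near the heterochromatin around the centromeres. The number of tested genes there is not known, so whether change was concentrated there could not be tested. Genes that fell lay in H3K9me2-rich regions more often than genes that rose. Of 121 bins of 1 Mb, the 24 with the most H3K9me2 held 41 of the 430 lower genes (9.53%) and 28 of the 684 higher genes (4.09%), with an odds ratio of 0.405 and p = 0.000321 by Fisher's exact test, two-sided. On chromosome 2 these bins held 17 lower and 5 higher genes. Among them were GRP-3 (start 2026162, TAIR10) and AT2G05914 (start 2263151) in one bin, both lower, and PR1 (start 6241704) in another. Without chromosome 2, an alternative chosen after seeing the data, 24 of 348 lower genes (6.90%) and 23 of 571 higher genes (4.03%) lay in such bins and the difference no longer passed (p = 0.0640, Fisher's exact test). The difference of −5.44 percentage points was −12.1 points among genes changed at least 2-fold (p = 8.16e-05, Fisher's exact test) and −1.59 points in the top 10% of bins (p = 0.0319, Fisher's exact test). Neighbouring genes are not independent, so these p-values can be too small.

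**Figure D3:**
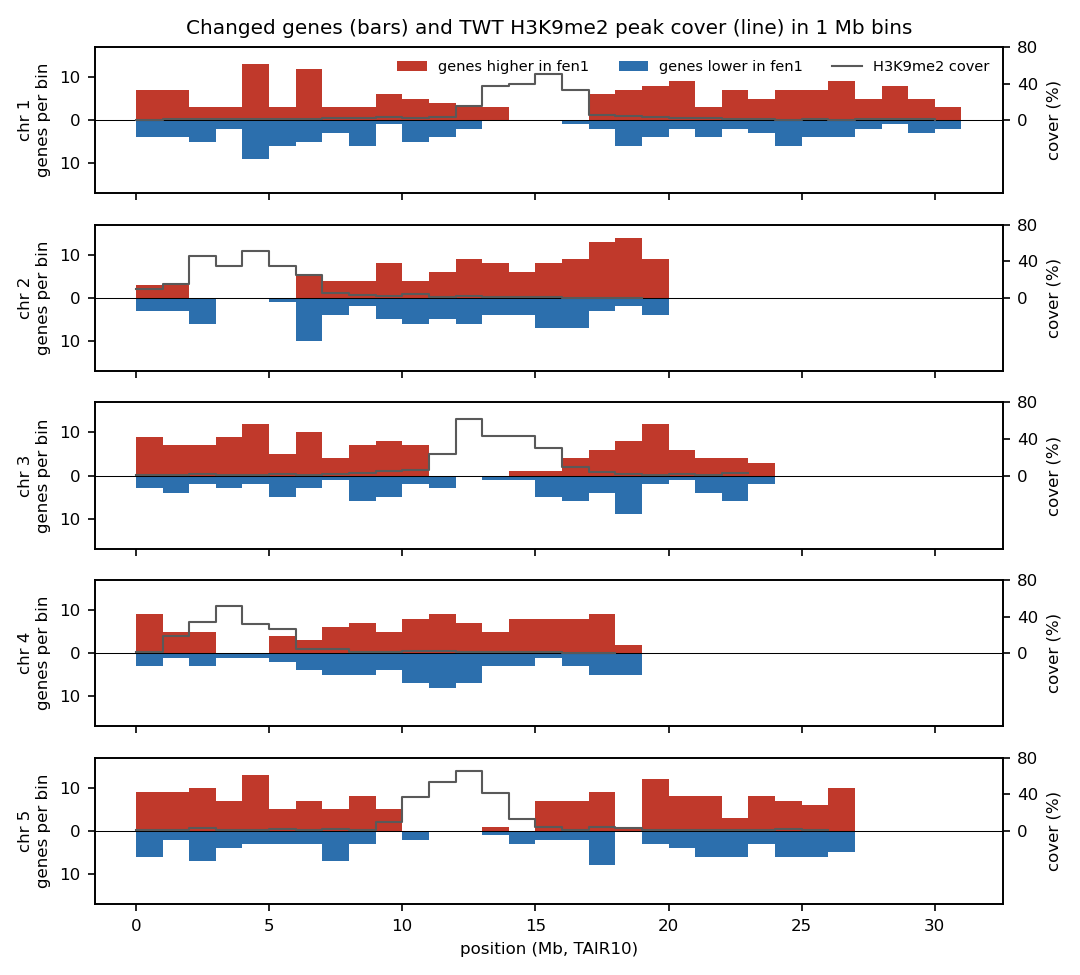
For each of the 5 chromosomes (horizontal axis, position in Mb, TAIR10), bars above and below 0 count the genes higher (red) and lower (blue) in fen1 per 1 Mb bin, and the grey line gives the percentage of the bin covered by TWT H3K9me2 peaks (right axis). Changed genes are sparse where the H3K9me2 line is high. The number of tested genes per bin is not known, so the bars give no share of genes changed. The 24 bins with the most H3K9me2 hold 28 higher and 41 lower genes.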

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

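The overlap of H3K4me3 with H3K27me3 peaks was the test set before its result was seen; its interval and the other overlaps were added after. Peaks were also called on the chloroplast genome, which has no histones and which no comparison above uses. There were 38 such H3K27me3 peaks, 36 H3K4me3 peaks and 6 H3K9me2 peaks. The 36 H3K4me3 peaks had a median score of 147 against 1204 for nuclear peaks of that list, whereas the 38 H3K27me3 peaks scored like nuclear ones, with medians of 124 and 125, and the 6 H3K9me2 peaks scored above them, with medians of 408 and 235. One candidate explanation is DNA that comes down at the same places whichever antibody is used. Of the 36 H3K4me3 peaks, 58.3% overlapped an H3K27me3 peak (exact 95% interval 40.8 to 74.5%), against a mean of 56.0% and an upper end of the central 95% of 72.2% in 10000 random placements. H3K27me3 peaks overlapped H3K4me3 peaks in 73.7% of cases (placements 62.8%, upper end 78.9%), and 5 of the 6 H3K9me2 peaks overlapped H3K27me3, 83.3% (placements 49.1%, upper end 83.3%). With so few peaks, shared and random places cannot be told apart. An even background of abundant plastid DNA was not tested and stays open, and no biological explanation was tested.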

How the results depend on the processing

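The score minimum, the quartiles, the dropped list members and the omission of chromosome 2 were chosen after the data were seen. With at least 2-fold changes the count fell from 1114 to 457 genes, 325 higher and 132 lower (the 10 genes at 0 in one genotype included), and at a q under 0.01 the lower genes fell from 430 to 248, because fewer genes meet a stricter limit. The call of the DNA damage list held under every alternative run. The seed list (2 genes at a q under 0.01) and both directions of the defence list (2 and 2 genes at 2-fold) lost theirs with fewer genes called, and 1 transposable element gene was left at 1 FPKM. The H3K27me3 difference lost its call in 6 alternatives, at 4.99 points (50% of the gene covered), 5.21 (1 kb upstream added), 3.25 (peaks of higher score), 4.12 (score of at least 100), 3.77 (quartiles of expression) and −2.55 (2-fold, reversed). The H3K4me3 difference lost its call at 2-fold (−6.40 points), where 457 genes enter, and kept it in the others. The small H3K9me2 difference reversed at −0.286 (50% covered), −0.0265 (higher score), −0.983 (score of at least 100) and −0.853 points (2-fold), never past the threshold. TWT levels under H3K27me3 passed only with 50% of the gene covered (−0.54). The overlap of H3K27me3 with H3K9me2 reversed among peaks of higher score (−4.16 and −6.72 points), and the position difference lost its call without chromosome 2 (−2.87 points), which removes 17 of 41 lower genes, and kept it at −12.1 points with 2-fold changes (p = 8.16e-05, Fisher's exact test) and at −1.59 points in the top 10% of bins (p = 0.0319, Fisher's exact test), against −5.44 in the report's setting. Beyond those named, the cause was not tested. For the 50 named genes with a fold change, all 150 values with a pseudocount kept their sign, and 54 moved by over 1.5 times. A q under 0.1 and rescaling by the median ratio were not run, as the genes not called have no values, and leaving out a replicate was not run, as values per library were not used. No paired analysis was possible because the columns hold 1 value per genotype. Unknown depth limits all genes of low FPKM.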

Other observations

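Among the tests of this part, that on paralogs was chosen only after a first form of it had been seen, that on neighbours not both marked by H3K27me3 after their share had been seen, and the 3 gene groups were noticed in these data and then tested on members other than those noticed first. The p-values of the 3 gene groups are unadjusted. Fisher's exact test takes members as independent, so these p-values can be too small where members rise together. Many genes of the response to low iron rose together in fen1. A list of 22 such genes was drawn up after the group was noticed. Of these, 16 were called, all higher. In the authors' deposited table the transcription factor genes BHLH38 and BHLH39 went from 5.86 to 40.8 FPKM and from 6.19 to 32.0 FPKM. The small iron-signalling peptide genes AT2G30766, AT1G47395 and AT1G47400 rose by a log2 of 2.94, 1.77 and 2.11 in the authors' deposited table. FRO3, a ferric reductase gene, rose by 1.26, NAS2, a nicotianamine synthase gene, by 2.06 and BTS, a regulator of the response, by 0.94 in the authors' deposited table. IRT1, FRO2 and FRU, which act in root iron uptake, were not listed. Related genes outside the 22 moved both ways. NAS3 (log2 −0.99) and NRAMP1 (log2 −0.48) were lower and NRAMP3 (log2 0.72) was higher in the authors' deposited table. Leaving out the 2 genes seen first, BHLH100 and AT2G30766, 14 of 20 members were higher (Fisher's exact test, two-sided, p = 7.70e-17). The 14 include the adjacent genes BHLH38 and BHLH39, and likewise AT1G47395 and AT1G47400. A hypothesis is that fen1 seedlings may be in a state of iron deficiency signalling. Iron content was not measured here, and why IRT1, FRO2 and FRU were not listed is open.

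Genes named for their specific expression in root hairs also rose. Of 18 genes that the reference table names root hair specific, 9 were called, all higher. Without RHS13, RHS14 and RHS16, which were seen first, 6 of 15 were higher (Fisher's exact test, two-sided, p = 5.79e-06). RHS19 went from 13.4 to 33.1 FPKM and RHS13 from 18.7 to 34.7 FPKM in the authors' deposited table. A hypothesis is that root hair genes rise as a group in fen1. A larger share of root tissue in the fen1 samples may also raise them and was not tested on its own. Of the 13 fixed root markers 1 was called, EXPA7, itself expressed in root hairs. None of the 19 fixed photosynthesis genes was called. Some photosynthesis genes outside that list, picked after their values were seen, were lower, such as PSAF (log2 −0.56 in the authors' deposited table).

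The indole phytoalexin genes gave no clear answer. CYP71A12, CYP71A13 and CYP82C2 of indole phytoalexin synthesis rose by a log2 of 3.66, 3.53 and 3.82, and PAD3 by 0.73, in the authors' deposited table. The hypothesis of a rise of the wider pathway was tested on 8 other members, of which 1, GSTF6, was higher (Fisher's exact test, two-sided, p = 0.242), too few to decide. The regulator WRKY33 was not listed.

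Neighbouring changed genes moved in the same direction more often than chance gives. Of 95 adjacent protein-coding pairs, 79 (83.2%) shared a direction, against a mean of 52.8% when directions were permuted (p = 0.0001, the smallest that 10000 permutations can give). Reads shared between overlapping genes could not be the whole cause, since 83.0% of the 94 pairs that do not overlap shared a direction. Reads shared between tandem paralogs are a second candidate explanation, as many pairs, such as LTP3 and LTP4, are copies, and a first filter on identical descriptions, after which 57 of 70 pairs shared a direction, left some copies in. Removing every pair with a shared description word or symbol start left 32 pairs, 2 of them still likely copies (AT4G12545 with AIR1, AT5G61590 with ERF104). Of the other 30 pairs, 24 (80%) shared a direction, above the 70% that ends the central 95% of permuted values (p = 0.0016, permutation test), which argues against paralogs as the whole cause, though distant copies may remain. A shared H3K27me3 domain is likewise not the whole cause, since 49 of the 61 pairs that do not both carry the mark shared a direction (80.3%, upper end of permuted values 65.6%, p = 0.0001, permutation test). Whether it adds to the pattern in the 33 pairs that both carry it, of which 29 shared a direction, stays open (Fisher's exact test against the other pairs, two-sided, p = 0.405).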
